A study of Mus musculus with 8 samples.

How the data were processed

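Sequencing of oligo-dT selected mRNA was done on a DNA nanoball platform, per the labels' protocols. Per the submitters' processing notes, reads were mapped with HISAT2 2.1.0 and Bowtie2 2.2.5, and expression was computed with RSEM 1.2.8. The mapping used the mouse build GRCm38.p6. The authors deposited RSEM expected counts, which may hold fractions where a read fits several transcripts. The authors deposited FPKM values (fragments scaled by transcript length and depth) for the same genes. The authors also deposited TPM values (transcript abundance scaled to a fixed sum). No further normalization step is recorded in the file headers.

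The values are in 2 tables, with 17051 genes for PBS and 17788 for the nanocage groups. Of these 16695 are in both, 356 only in the PBS table and 1093 only in the other. No value is held for 365 genes of the PBS table. The 16547 genes with values in all 8 libraries were used. Of their expected counts 5.09% were not whole (tolerance 1e-09), and 1269 genes had such split counts, which mark reads shared with near-identical copies. Names marked with split counts are uncertain. Gene IDs were matched to the RefSeq annotation of GRCm38.p6 for 16505 of 16547 genes, of which 16422 are protein-coding, and coordinates come from there. Every deposited column was used. Whether counting used strand is not stated, so overlapping and antisense genes cannot be told apart.

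Expected counts were rounded and analysed with edgeR 4.0.16 in R 4.3.3. The filterByExpr function kept 13953 genes, and TMM factors scaled the libraries. All 8 libraries entered 1 quasi-likelihood fit with a mean per group, and each comparison was a contrast of group means. These were each nanocage against PBS, the 3 pairs of nanocages, and the mean of the 3 nanocages against PBS. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, with a threshold of 0.05. The common dispersion was 0.00718, a biological coefficient of variation of 8.47%, with 4 residual and 5.63 prior degrees of freedom. Standard errors are the log2 fold change divided by the square root of the F statistic, and intervals are at 95%. Levels are CPM on TMM-scaled library sizes, and log2 CPM for the principal components used a prior count of 2. With 3 counts as the floor, a gene with no count in a library lies below 0.191 to 0.22 CPM. Intervals and floors cover counting error only where they concern a single library.

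Gene lists, 57 in number, were fixed from textbook knowledge before the data were examined. Of these 53 had at least 5 tested members. Each was tested in the 7 contrasts with camera (preset correlation 0.01), with camera using an estimated correlation, and with fry, all in limma 3.58.1, and p-values were adjusted over the lists of a contrast. Camera compares a list with all other genes, and fry tests whether its members move 1 way. The camera test called 177 of 371 combinations, 55 up and 122 down, and fry 137. With an estimated correlation camera called 0 of 371. Counts of members past the threshold are given over all genes and, where they differ, adjusted over the list alone.

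The genes named were chosen by a rule. A gene needed an adjusted p under 0.05, at least 5 CPM in the higher group, every library of 1 group above every library of the other, and a name that is not a predicted gene, clone or pseudogene. The first set is the 6 largest rises and falls against PBS and the 4 largest between nanocages. The next set holds up to 4 members with the lowest adjusted p of each list called by camera or with at least 3 members past the threshold, and from it those with stable calls are named by preference, a choice made after their values were seen. The last set is 22 genes of oxidant removal, iron storage, muscle stress, inflammation and matrix that are given in every comparison. Where fewer than 3 genes passed in a direction, the 3 with the lowest p are given as not passed. A gene without counts in a group is given as a bound against the floor.

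For the length trend, effective lengths were taken from the ratio of counts to FPKM for genes with at least 10 counts. A spline with 4 degrees of freedom on log2 length was fitted to each library's log2 counts relative to the mean of the 8 libraries, over genes with a mean of at least 50 counts, and entered as an offset. For camera the same trend was subtracted from log2 CPM. This correction was chosen after the trend was seen. Adding it lowered the Spearman correlation to between -0.02 and 0.01. Simulated counts carried the trend in the PBS libraries alone, as deviation from the mean of the 8 libraries, with no other change. They gave 88, 115 and 22 false calls of 13953 in the comparisons of iFTn-M4, iFTn-R4 and iFTn-MR4 with PBS. In edgeR with the offset they gave 0, 0 and 1. The nanocage part of the trend was left out, and without changed genes the adjusted threshold is stricter than in the data. These counts therefore do not measure the number of false calls in the data. Unchanged groups against the shared PBS libraries were simulated 100 times.

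Alternatives were DESeq2 1.42.0, limma-voom, limma-trend on log2 of TPM with a pseudocount of 1 (13232 genes with a TPM of at least 1 in 2 libraries), RLE factors, library size alone, a mean of at least 10 counts, no filter on low counts, only the groups compared, no haemoglobin genes, each library left out in turn, a log2 fold change of at least 1, the length offset, and no genes with split counts. The scripts were tested on simulated data with 200 changed genes. For iFTn-MR4 against PBS the fit recovered 67.2% of genes changed 1.5-fold, 91% of those changed 2-fold and 100% of those changed 4-fold. These were 45, 61 and 66 genes, beside 22 false calls among the 13843 genes fitted. For iFTn-MR4 against iFTn-M4 it recovered 42, 60 and 66 genes, beside 18 false calls. In both comparisons false calls were a larger share of all calls than the adjusted p threshold. For iFTn-M4 against PBS, where no gene was changed, 3 genes were called. The list test of limma's camera recovered the shifted list (adjusted p = 1.97e-55) and called 0 of the other lists. Simulated genes were drawn independently, so this does not test how correlation among the members of a list affects its calls. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. Genes listed in 1 table only were not used in the comparisons. Some genes that meet the naming rule are not reported here. FPKM values were used only for effective lengths.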

Results

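The series measured RNA from mouse hearts after ischemia-reperfusion by sequencing of oligo-dT selected mRNA on a DNA nanoball platform. Its title names protein nanocage-based nanozymes for scavenging superoxide inside cells. Each of the 4 groups has 2 libraries. They are PBS and the nanocages iFTn-MR4, iFTn-M4 and iFTn-R4. The nanocages were given as 2 doses of 2.5 mg/kg protein, and heart tissue was taken after 3 days. Total expected counts were 15729385 and 15478158 for PBS, 13908143 and 14537959 for iFTn-M4, 15244434 and 14742922 for iFTn-R4, and 13618588 and 13884035 for iFTn-MR4. Between 15520 and 15849 genes had a count in a library. The alpha myosin heavy chain gene Myh6 alone took 1.17% to 2.82% of a library's counts. Haemoglobin genes took 0.022% to 0.11%, and mitochondrially encoded genes were not in the tables. The labels do not say that the 2 libraries of a group come from separate animals, so p-values measure only the spread between these samples. The PBS libraries are in a table of their own, so each comparison with PBS is also a comparison between tables.

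The first principal component of log2 CPM (counts scaled to library size), with 57.7% of the variance, ordered the groups. PBS libraries lay at -46.3 and -44.2, iFTn-R4 at -14.1 and -7, iFTn-M4 at 15 and 23.8, and iFTn-MR4 at 37.4 and 35.2. Component 2 held 13.4% and separated iFTn-R4, at -23.1 and -23.3, from PBS and iFTn-MR4. Replicates of iFTn-R4 lay furthest apart, with a chi-square per degree of freedom of 16.02 against 7.21 for PBS, 6.37 for iFTn-M4 and 4.95 for iFTn-MR4. Below, levels are means ± SD of 2 libraries in CPM, and log2 fold changes are given ± SE from edgeR's quasi-likelihood fit of all 8 libraries. A gene is said to rise or fall only where its Benjamini-Hochberg adjusted p is under 0.05 among 13953 tested genes.

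**Figure D1:**
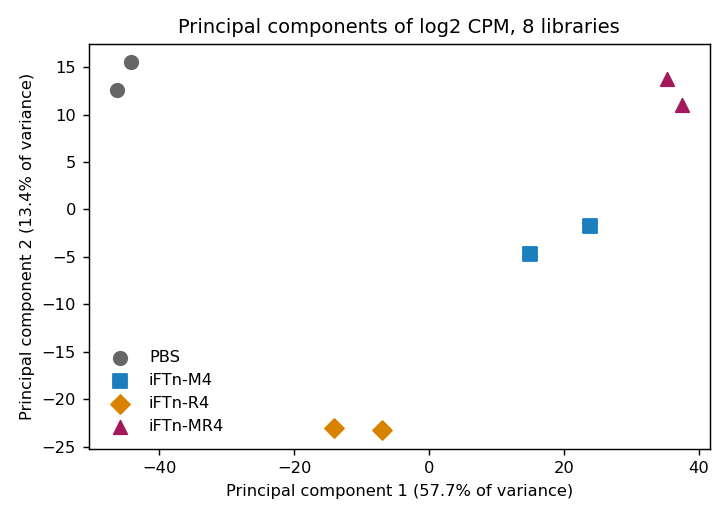
Principal components of log2 CPM, with 1 point per library and component 1 (57.7% of variance) against component 2 (13.4%). The 2 libraries of each group lie side by side, PBS at the low end and iFTn-MR4 at the high end of component 1.

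Fold changes against PBS followed transcript length. Spearman correlations were 0.39 for iFTn-M4, 0.50 for iFTn-R4 and 0.35 for iFTn-MR4, against 0.07, 0.04 and 0.01 for iFTn-MR4 against iFTn-M4, iFTn-MR4 against iFTn-R4 and iFTn-R4 against iFTn-M4. The median log2 fold change of the longest quintile of genes exceeded that of the shortest by 0.54, 0.55 and 0.58 in the 3 comparisons against PBS. Of 35 cytosolic ribosomal protein genes, 25 fell in iFTn-M4 against PBS and 11 did once a length offset was added. In iFTn-R4 16 fell, and in edgeR with the offset 0 fell and 2 rose.

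**Figure D2:**
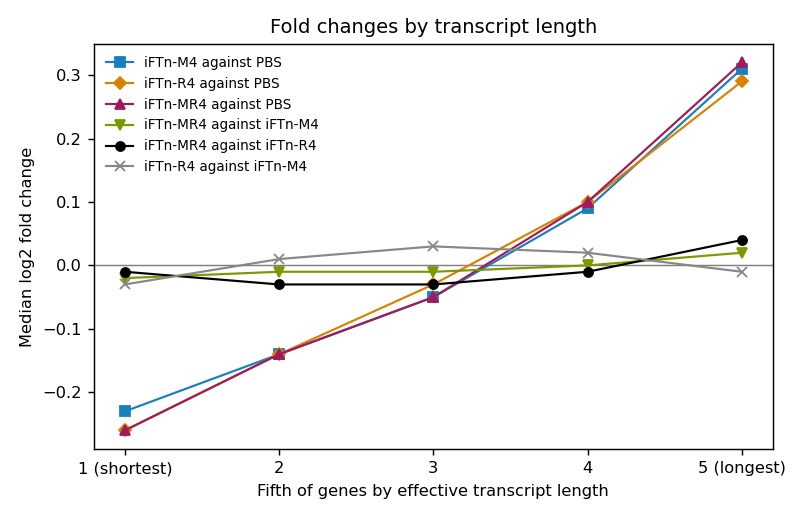
Median log2 fold change (vertical axis) in each quintile of genes by effective transcript length (horizontal axis), with 1 line for each of the 6 comparisons. The 3 lines for comparisons against PBS climb from between -0.26 and -0.23 to between 0.29 and 0.32, and those among nanocages stay near 0.

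In iFTn-M4 against PBS, all 28 tested genes of the interferon response list fell (camera adjusted p = 3.27e-11, adjusted p = 0.565 with an estimated correlation), with a median log2 fold change of -1.43 (quartiles -1.73 to -1.11). Igtp, a GTPase of antimicrobial defence that is not on the list, fell 24.4-fold, at 39.1 ± 7.49 against 954 ± 122 CPM (log2 fold change -4.61 ± 0.15, edgeR adjusted p = 3.8e-07). It lies at Entrez gene 16145, chromosome 11, 58199556 to 58207592 of GRCm38.p6, and its expected counts were split with near copies, so its size is uncertain. Ankrd2, a stretch-responsive muscle protein, fell further, at 0.459 ± 0.161 against 19.5 ± 7.11 CPM (-5.39 ± 0.37, 95% interval -6.22 to -4.55, Entrez gene 56642, chromosome 19, 42035917 to 42045111). Col11a1, a fibrillar collagen chain, rose at 9.73 ± 2.84 against 1.36 ± 0.226 CPM (2.83 ± 0.34, edgeR adjusted p = 0.000243, Entrez gene 12814, chromosome 3, 114030479 to 114220756). Of all tested genes, 2764 rose and 2981 fell in edgeR, against 4102 and 1725 in limma-trend on TPM, where the median of all genes shifted to 0.14. Without iFTn-M4 replicate 2 the total was 3560.

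Within the interferon list, the regulator Irf1 went from 124 ± 2.81 to 48.1 ± 2.71 CPM (-1.37 ± 0.09). The tetherin gene Bst2 (-1.92 ± 0.11) and the GTPase Gbp2 (-2.19 ± 0.16) fell with it. Outside the list, Gbp10 (-4.57 ± 0.44, split counts) and the tryptophan-degrading enzyme Ido1 (-4.22 ± 0.52) fell as well. Among 32 cytokines and chemokines 22 fell, 2 rose and 8 did not pass, or 24 and 2 when adjusted over the list alone (camera adjusted p = 4.48e-05, adjusted p = 0.395 with an estimated correlation). The monocyte attractants Ccl2 (24 ± 5.15 against 103 ± 30.6 CPM, -2.1 ± 0.23) and Ccl7 (-2.28 ± 0.27), the T cell attractant Cxcl9 (-3.05 ± 0.21) and the neutrophil attractant Cxcl3 (-4.14 ± 0.53) all fell. So did the inflammatory cytokines Il1b (-2.04 ± 0.36) and Il6 (-2.4 ± 0.65). Neutrophil genes fell in 11 of 16 cases, with a median of -1.74 (camera adjusted p = 7.32e-05, adjusted p = 0.47 with an estimated correlation). Examples are the decoy receptor Il1r2 (-2.83 ± 0.27), the growth factor receptor Csf3r (-1.24 ± 0.18) and the alarmin S100a8 (-1.27 ± 0.42, edgeR adjusted p = 0.0358).

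Of 15 fetal and wall stress genes 12 fell and 1 rose (camera adjusted p = 0.000712, adjusted p = 0.47 with an estimated correlation). The natriuretic peptides Nppa (936 ± 4.35 against 2075 ± 275 CPM, -1.15 ± 0.12) and Nppb (-1.94 ± 0.12), markers of wall stress, fell. Outside the list, the NAD-synthesis kinase Nmrk2 fell (-4.24 ± 0.3). Heat shock genes fell in 14 of 17 cases (camera adjusted p = 2.25e-06, adjusted p = 0.47 with an estimated correlation), including the small chaperone Hspb1 (147 ± 5.95 against 752 ± 61 CPM, -2.36 ± 0.17). The unfolded protein response list fell in 17 of 22 cases (camera adjusted p = 3.33e-08, adjusted p = 0.395 with an estimated correlation), with the endoplasmic reticulum proteins Sdf2l1 (-1.54 ± 0.11) and Manf (-1.22 ± 0.09). Glycolysis gave 13 falls and 4 rises of 20 (camera adjusted p = 0.00164, adjusted p = 0.395 with an estimated correlation), led by the glucose transporter Slc2a1 (-2.13 ± 0.11) and the lactate exporter Slc16a3 (-2.7 ± 0.2). Myh6 rose 1.68-fold to 24830 ± 1876 CPM and the beta chain Myh7 rose as well (1.27 ± 0.32), both with split counts. The calcium pump Atp2a2 (0.94 ± 0.12) and the potassium channel subunit Kcnip2 (1.21 ± 0.09) rose.

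Fibroblast genes rose in 13 of 16 cases, with a median of 0.83 (camera adjusted p = 1.71e-05, adjusted p = 0.358 with an estimated correlation). The small proteoglycans Dcn (0.99 ± 0.1) and Lum (1.08 ± 0.09) and the matrix protein Dpt (1.06 ± 0.08) are examples. Collagens and matrix rose in 19 of 33 cases and fell in 3 (camera adjusted p = 0.00225, adjusted p = 0.75 with an estimated correlation, fry adjusted p = 0.0587). Among them were Col3a1 (0.86 ± 0.17) and Col1a1 (0.74 ± 0.21). Outside the list, Col6a6 (2.79 ± 0.17, split counts), Col24a1 (2.55 ± 0.53) and the matricellular gene Postn (1.01 ± 0.13) rose. The channel subunit Cngb3 (2.61 ± 0.34), the cadherin Cdh23 (2.23 ± 0.16) and the proton pump subunit Atp6v0d2 (2.22 ± 0.39) rose alongside. The metalloproteinase inhibitor Timp1 (-2.01 ± 0.19) fell, as did the secreted phosphoprotein Spp1 (-0.84 ± 0.19). Acta2, the smooth muscle actin, did not pass (-0.57 ± 0.27).

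Superoxide and peroxide removal genes gave 9 falls, no rise and 13 that did not pass of 22 in edgeR (camera adjusted p = 0.0186, adjusted p = 0.565 with an estimated correlation, 0.684 with the length trend subtracted). With the length offset 3 rose and 4 fell, and the median moved from -0.13 to 0.03. Thioredoxin Txn1 (97.7 ± 3.63 against 171 ± 1.56 CPM, -0.81 ± 0.07), its reductase Txnrd1 (-0.98 ± 0.1), glutathione reductase Gsr (-0.99 ± 0.13) and glutathione peroxidase Gpx1 (-0.39 ± 0.1) fell. Haem oxygenase Hmox1 fell (-0.7 ± 0.23). The superoxide dismutases Sod1 (-0.14 ± 0.09) and Sod2 (-0.03 ± 0.09), catalase Cat (-0.04 ± 0.17), the quinone reductase Nqo1 (0.13 ± 0.12) and the ferritin chains Fth1 (0.05 ± 0.12) and Ftl1 (0.06 ± 0.12, split counts) did not pass. By edgeR adjusted p, the call of Gpx1 (0.11 to 0.113 without PBS replicate 1 or iFTn-M4 replicate 2), Hmox1 (0.0979 to 0.23 without either PBS library or iFTn-M4 replicate 2), S100a8 (0.0539 to 0.128 without either PBS library, iFTn-M4 replicate 2 or either iFTn-MR4 library), Spp1 (0.0562 to 0.0642 without PBS replicate 1 or iFTn-M4 replicate 2), Col1a1 (0.0667 to 0.154 without either PBS library or iFTn-M4 replicate 1), Il6 (0.0749 to 0.146 without PBS replicate 2 or either iFTn-M4 library) and of Myh7 (0.075 without iFTn-M4 replicate 1) ended with a library left out. A call ended also with the length offset for Gpx1 (0.375), Hmox1 (0.136) and Col1a1 (0.115), in DESeq2 for Hmox1 (0.0972) and S100a8 (0.144), in limma-trend on TPM for Gpx1 (0.122) and Hmox1 (0.112). Leaving out a library moved the fold over 1.5 times for Atp6v0d2 (log2 3.21 without PBS replicate 1), Il6 (log2 -3.01 to -1.36 without either PBS library), Myh7 (log2 2.01 without PBS replicate 2), Col24a1 (log2 1.87 without iFTn-M4 replicate 1), Cxcl3 (log2 -4.76 without iFTn-M4 replicate 1), Il1b (log2 -2.71 without iFTn-M4 replicate 1), S100a8 (log2 -2.63 to -0.58 without either iFTn-M4 library) and Ido1 (log2 -4.9 without iFTn-M4 replicate 2). On log2 of TPM the fold moved over 1.5 times for Col11a1 (1.28), Col6a6 (1.92), Cngb3 (1.43), Col24a1 (1.02), Cdh23 (1.45), Ankrd2 (-4.16), Gbp10 (-3.69), Ido1 (-2.61), Cxcl3 (-3.17) and Il6 (-1.63).

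iFTn-R4 differed from PBS in fewer genes, with 1945 that rose and 2151 that fell, against 849 and 1102 with the length offset and 1262 and 1266 with only the groups compared. Of the main calls 37% remained with the offset. Scaling by library size alone gave 2490 and 1575, and limma-trend on TPM 4444 and 658 with a median of all genes of 0.211. The total was 2156 without PBS replicate 1 and 2055 without PBS replicate 2. The class II transactivator Ciita, which switches on antigen presentation genes, fell 2.72-fold, at 6.76 ± 1.4 against 18.5 ± 1.36 CPM (-1.44 ± 0.18, edgeR adjusted p = 0.000947, Entrez gene 12265, chromosome 16, 10480014 to 10531064). All 8 tested genes of antigen presentation by MHC class II fell, with a median of -1.37 (camera adjusted p = 9.23e-05, adjusted p = 0.576 with an estimated correlation). Ankrd2 fell here as well, at 2.21 ± 0.317 against 19.5 ± 7.11 CPM (-3.13 ± 0.29), and so did Nmrk2 (-3.2 ± 0.27). Complement C3, the central complement protein, rose 2.78-fold, at 858 ± 7.58 against 308 ± 48.7 CPM (1.48 ± 0.11, Entrez gene 12266, chromosome 17, 57203967 to 57228136).

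Of the 28 interferon response genes 20 fell, or 24 when adjusted over the list alone, with a median of -0.81 (camera adjusted p = 2.94e-07, adjusted p = 0.576 with an estimated correlation, fry adjusted p = 0.0711). Bst2 fell 2.25-fold (-1.17 ± 0.1), with Gbp2 (-1.13 ± 0.15) and the nucleic acid sensor Zbp1 (-1.18 ± 0.16). Besides Ciita, the MHC class II list includes the beta chain gene H2-Ab1 (40 ± 18 against 125 ± 29.9 CPM, -1.64 ± 0.25), the peptide loader H2-DMa (-1.14 ± 0.17) and the protease Ctss (-0.8 ± 0.1). Cytokines and chemokines gave 10 falls and 1 rise of 32 (camera adjusted p = 0.00774, adjusted p = 0.576 with an estimated correlation, 0.081 with the length trend subtracted, fry adjusted p = 0.0643). Falls included Cxcl9 (-1.73 ± 0.19). Outside the list, the eosinophil attractant Ccl24 (-2.88 ± 0.68), the lipoxygenase Alox15 (-2.58 ± 0.48) and Ido1 (-2.36 ± 0.42) also fell. The neutrophil list had 1 rise and 3 falls of 16 and was not called by camera (adjusted p = 0.747), its median (-0.07) and mean (0.22) differing in sign. Il1b (-0.64 ± 0.32), Il6 (-1.3 ± 0.57), Ccl2 (-0.62 ± 0.21, edgeR adjusted p = 0.0513), S100a8 (0.36 ± 0.38) and Spp1 (0.03 ± 0.19) did not pass.

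Nppa (-0.98 ± 0.12), Nppb (-1.64 ± 0.12), the cardiac actin Actc1 (5040 ± 356 against 11960 ± 19.2 CPM, -1.25 ± 0.12) and tropomyosin Tpm1 (-0.77 ± 0.1) fell. Myh6 did not pass (-0.21 ± 0.13, split counts), while Myh7 rose (1.8 ± 0.33, split counts). Respiratory complex I gave 8 falls and no rise of 37 in edgeR (camera adjusted p = 0.000504, adjusted p = 0.687 with an estimated correlation, 0.269 with the length trend subtracted, fry adjusted p = 0.19), with Ndufc2 (-0.6 ± 0.09) and Ndufs7 (-0.62 ± 0.1). With the length offset 4 fell and 1 rose. Glycolysis gave 15 falls and no rise of 20 in edgeR (camera adjusted p = 1.23e-06, adjusted p = 0.21 with an estimated correlation), again with Slc2a1 (-1.3 ± 0.11) and the phosphofructokinase Pfkp (-0.86 ± 0.08). Heat shock genes fell in 11 of 17 cases (camera adjusted p = 1.62e-05, adjusted p = 0.576 with an estimated correlation), among them Hspb1 (-1.66 ± 0.17). Unfolded protein response genes fell in 13 of 22 (camera adjusted p = 0.000106, adjusted p = 0.576 with an estimated correlation), among them Manf (-0.64 ± 0.09).

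Fibroblast genes rose in 12 of 16 cases (camera adjusted p = 0.000106, adjusted p = 0.251 with an estimated correlation) and collagens and matrix in 13 of 33 (camera adjusted p = 0.000146, adjusted p = 0.606 with an estimated correlation, fry adjusted p = 0.108). Examples are Dcn (0.8 ± 0.1), the scavenger receptor Scara5 (1.26 ± 0.16) and Col3a1 (0.55 ± 0.17). Outside these lists, the gelatinase Mmp2 (0.79 ± 0.1), Col11a1 (2.3 ± 0.34) and Postn (0.5 ± 0.13) rose. Col1a1 (0.56 ± 0.21) and Acta2 (-0.56 ± 0.27) did not pass. Timp1 fell (-0.7 ± 0.18). The retinoic acid hydroxylase Cyp26b1 (94.3 ± 98.5 against 8.38 ± 1.29 CPM, 3.49 ± 0.78), the aminopeptidase Lvrn (2.87 ± 0.57), Cngb3 (2.15 ± 0.34), the glycoprotein Myoc (2.02 ± 0.4) and the T cell granzyme Gzma (1.76 ± 0.27) rose. Sprr2a1, a small proline-rich protein, had no count in PBS and 6.56 CPM in iFTn-R4, at least 33.8-fold higher against a floor of 3 counts per library, but its counts were split in 1 library and its change is uncertain. The nucleotidase Entpd4 had 8.54 CPM in PBS and none in iFTn-R4, at least 42.1-fold lower, but its counts were split in 5 libraries and its change is uncertain, and without PBS replicate 2 it did not pass (edgeR adjusted p = 0.0625). Superoxide and peroxide removal gave 7 falls and 1 rise of 22 (camera adjusted p = 0.00453, adjusted p = 0.576 with an estimated correlation, 0.928 with the length trend subtracted), or 4 falls and 1 rise with the length offset, where the median turned from -0.25 to 0.04. Txn1 (-0.63 ± 0.07), Sod2 (-0.32 ± 0.09) and Gpx1 (-0.36 ± 0.1) fell. Outside the list, the NADPH oxidase Nox4 rose (1.13 ± 0.23), while the NADPH oxidase subunits Cyba (-0.44 ± 0.08), Ncf4 (-0.45 ± 0.14) and Ncf1 (-0.56 ± 0.18) fell. With the length offset Nox4 still passed (edgeR adjusted p = 0.0194), and Cyba (0.395), Ncf4 (0.351) and Ncf1 (0.094) did not. Sod1 (-0.24 ± 0.09), Cat (0.1 ± 0.17), Hmox1 (-0.38 ± 0.23), Nqo1 (0.14 ± 0.12), Fth1 (-0.17 ± 0.12) and Ftl1 (-0.34 ± 0.12, split counts) did not pass. By edgeR adjusted p, the call of Cyp26b1 (0.0583 to 0.0716 without either PBS library), Myoc (0.052 without PBS replicate 1), Ccl24 (0.0981 without PBS replicate 1), Gpx1 (0.0576 to 0.175 without PBS replicate 1, iFTn-R4 replicate 2 or either iFTn-MR4 library), Postn (0.0722 to 0.1 without either PBS library or iFTn-R4 replicate 1), Sod2 (0.0527 to 0.17 without either PBS library, iFTn-R4 replicate 1 or either iFTn-MR4 library), Col3a1 (0.101 to 0.149 without either PBS library or iFTn-R4 replicate 1) and of Timp1 (0.0656 to 0.0838 without either PBS library or iFTn-R4 replicate 2) ended with a library left out. A call ended also with the length offset for Gpx1 (0.697), Col3a1 (0.225) and Timp1 (0.198), in limma-voom for Cyp26b1 (0.0591) and Ccl24 (0.0665), in limma-trend on TPM for Gpx1 (0.405), Timp1 (0.0926) and Sod2 (0.572), with only the groups compared for Gpx1 (0.0748), Col3a1 (0.0734) and Sod2 (0.0942), with library size alone for Gpx1 (0.0592). Leaving out a library moved the fold over 1.5 times for Lvrn (log2 1.96 to 3.81 without PBS replicate 1 or iFTn-R4 replicate 2), Ccl24 (log2 -3.59 to -1.4 without either PBS library), Alox15 (log2 -1.68 without PBS replicate 1), Myh7 (log2 2.53 without PBS replicate 2), Cyp26b1 (log2 1.55 to 4.27 without either iFTn-R4 library) and Ido1 (log2 -3.41 to -1.75 without either iFTn-R4 library). On log2 of TPM the fold moved over 1.5 times for Cyp26b1 (2.77), Lvrn (1.35), Col11a1 (0.97), Cngb3 (1.17), Ccl24 (-1.87), Ido1 (-1.74) and Ciita (-0.81).

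iFTn-MR4 stood furthest from PBS, with 3430 genes that rose and 3666 that fell, against 4251 and 2566 in limma-trend on TPM (median of all genes 0.109). Ccl2, which draws monocytes into tissue, fell 8.91-fold, at 11.5 ± 2.4 against 103 ± 30.6 CPM (-3.16 ± 0.25, edgeR adjusted p = 1.72e-05, Entrez gene 20296, chromosome 11, 82035577 to 82037452). Bst2, which holds budding virus at the cell surface, fell 4.81-fold, at 41.6 ± 1.22 against 200.1 ± 14.4 CPM (-2.26 ± 0.11, Entrez gene 69550, chromosome 8, 71534255 to 71537472). Nppa, the atrial natriuretic peptide, fell 6.54-fold, at 317 ± 47.4 against 2075 ± 275 CPM (-2.71 ± 0.13, Entrez gene 230899, chromosome 4, 148000722 to 148002074). Atp2a2, the pump that returns calcium to the sarcoplasmic reticulum, rose 2.39-fold, at 13720 ± 489.8 against 5743 ± 187 CPM (1.26 ± 0.12, Entrez gene 11938, chromosome 5, 122453513 to 122502225).

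All 28 interferon response genes fell, with a median of -2.07 (camera adjusted p = 2.87e-12, adjusted p = 0.472 with an estimated correlation). They include the regulator Irf7 (-2.3 ± 0.14). Outside the list, Igtp (-5.16 ± 0.16) and Gbp10 (-5.07 ± 0.47) fell, both with split counts. Cytokines and chemokines fell in 24 of 32 cases and rose in 2 (camera adjusted p = 3.5e-06, adjusted p = 0.385 with an estimated correlation). Ccl7 (-3.36 ± 0.3), Cxcl9 (-3.41 ± 0.22), Cxcl3 (-5.34 ± 0.62), Il1b (-2.27 ± 0.37) and Il6 (-3.62 ± 0.76) fell. The level of Il6 in iFTn-MR4 was 0.447 ± 0.418 CPM, near the floor, so the size of its fall is uncertain. NF-kB targets fell in 17 of 22 cases and rose in 1 (camera adjusted p = 8.63e-05, adjusted p = 0.385 with an estimated correlation), for example Bcl3 (-1.61 ± 0.1). Neutrophil genes fell in 12 of 16 (camera adjusted p = 0.000401, adjusted p = 0.472 with an estimated correlation), for example Il1r2 (-3.73 ± 0.3), Slfn4 (-3.26 ± 0.18, split counts) and S100a8 (-1.86 ± 0.45). Of 22 monocyte and infiltrating macrophage genes 16 fell and 2 rose (camera adjusted p = 6e-04, adjusted p = 0.464 with an estimated correlation), with the Fc receptor Fcgr1 (-1.68 ± 0.1), the galectin Lgals3 (-0.96 ± 0.09) and Spp1 (198 ± 58.6 against 787 ± 126 CPM, -1.99 ± 0.2). Cell cycle genes fell in 34 of 36 cases (camera adjusted p = 4.25e-08, adjusted p = 0.547 with an estimated correlation), with the replicative helicase subunits Mcm2 (-1.25 ± 0.16), Mcm3 (-1.19 ± 0.15) and Mcm6 (-1.01 ± 0.14).

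Of 31 fatty acid oxidation genes 19 rose and none fell in edgeR (camera adjusted p = 0.000158, adjusted p = 0.63 with an estimated correlation, fry adjusted p = 0.0638), among them the regulator Ppara (96.9 ± 0.866 against 42.5 ± 4.87 CPM, 1.19 ± 0.1), its coactivator Ppargc1a (1.01 ± 0.1) and the dehydrogenase Acadm (0.66 ± 0.11). TCA cycle genes rose in 15 of 22 cases and fell in 1 (camera adjusted p = 0.000373, adjusted p = 0.63 with an estimated correlation), with Sdha (0.73 ± 0.09) and Idh2 (0.78 ± 0.12). Calcium cycling and ion channel genes rose in 13 of 21 (camera adjusted p = 0.00397, adjusted p = 0.515 with an estimated correlation), with the release channel Ryr2 (0.95 ± 0.15) and Kcnip2 (1.55 ± 0.09). Complex I gave 9 rises and 1 fall of 37 (camera adjusted p = 0.0193, adjusted p = 0.754 with an estimated correlation, fry adjusted p = 0.255) and 32 rises with the length offset, among them Ndufs1 (0.64 ± 0.1). Myh6 rose 1.91-fold to 28290 ± 1056 CPM (0.94 ± 0.13) and Myh7 rose (1.93 ± 0.33), both with split counts. The atrial myosin light chain Myl4 (3.07 ± 0.7), the protease inhibitor A2m (3.05 ± 0.36), Col6a6 (2.67 ± 0.17, split counts), Cngb3 (2.66 ± 0.34), Cdh23 (2.64 ± 0.16) and the kinase anchor Akap5 (2.49 ± 0.37) rose too.

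Ankrd2 fell from 19.5 ± 7.11 to 0.187 ± 0.0506 CPM (-6.64 ± 0.44). The lower level is under the floor of 3 counts in the iFTn-MR4 libraries (0.22 and 0.216 CPM), so the size of this fall is uncertain. The carbonic anhydrase Car9 (-4.66 ± 0.42), the AP-1 subunit Fosl1 (-4.62 ± 0.38), the proto-oncogene Myc (-2.28 ± 0.12), the cytokine Gdf15 (-3.21 ± 0.23) and Nppb (-2.12 ± 0.12) fell as well. Heat shock genes fell in 14 of 17 cases (camera adjusted p = 7.53e-05, adjusted p = 0.472 with an estimated correlation), with Hspb1 at -2.19 ± 0.17. Unfolded protein response genes fell in 18 of 22 (camera adjusted p = 2.6e-07, adjusted p = 0.385 with an estimated correlation), with the disulfide isomerase Pdia4 at -1.33 ± 0.08. Glycolysis gave 12 falls and 5 rises of 20 (camera adjusted p = 0.0281, adjusted p = 0.385 with an estimated correlation, 0.106 with the length trend subtracted), with Slc2a1 at -2.32 ± 0.12. Fibroblast genes rose in 12 of 16 cases (camera adjusted p = 0.000265, adjusted p = 0.385 with an estimated correlation), for example Dcn (1.1 ± 0.1) and the actin-severing gelsolin Gsn (1.54 ± 0.14). Collagens and matrix split into 10 rises and 9 falls of 33 and were not called by camera (adjusted p = 0.888). Col3a1 (0.52 ± 0.17) and, outside the list, Postn (0.54 ± 0.13) rose, and Col1a1 did not pass (0.16 ± 0.21). Timp1 (32 ± 3.22 against 248 ± 4.39 CPM, -2.95 ± 0.2), Acta2 (-1.12 ± 0.27) and the connective tissue factor Ccn2 (-2.44 ± 0.12) fell.

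Superoxide and peroxide removal gave 11 falls and 1 rise of 22, or 7 and 5 with the length offset (camera adjusted p = 0.0462, adjusted p = 0.515 with an estimated correlation, 0.789 with the length trend subtracted). Targets of the antioxidant regulator NRF2 fell in 17 of 26 cases and rose in 4 (camera adjusted p = 0.00433, adjusted p = 0.385 with an estimated correlation). Txn1 (74.2 ± 1.91 against 171 ± 1.56 CPM, -1.2 ± 0.07), Txnrd1 (-1.01 ± 0.1), Gsr (-1.14 ± 0.13), the sulfiredoxin Srxn1 (-1.05 ± 0.1), Gpx1 (-0.69 ± 0.1), Hmox1 (89.7 ± 17.6 against 312 ± 4.36 CPM, -1.8 ± 0.24) and Ftl1 (-0.7 ± 0.12, split counts) fell. Sod1 (-0.15 ± 0.09), Sod2 (0.23 ± 0.09, edgeR adjusted p = 0.0657), Cat (0.12 ± 0.17), Nqo1 (0.25 ± 0.12) and Fth1 (0.00 ± 0.12) did not pass. By edgeR adjusted p, the call of Col3a1 (0.0769 to 0.189 without either PBS library or iFTn-MR4 replicate 1), S100a8 (0.0597 without iFTn-MR4 replicate 1), Postn (0.0688 without iFTn-MR4 replicate 1) and of Acta2 (0.0725 without iFTn-MR4 replicate 1) ended with a library left out. A call ended also with the length offset for Col3a1 (0.25). Leaving out a library moved the fold over 1.5 times for Il6 (log2 -5.12 to -2.58 without either PBS library or either iFTn-MR4 library), Akap5 (log2 3.1 without PBS replicate 2), Myh7 (log2 2.67 without PBS replicate 2) and Myl4 (log2 1.45 to 3.83 without either iFTn-MR4 library). On log2 of TPM the fold moved over 1.5 times for A2m (1.31), Col6a6 (1.8), Cngb3 (1.42), Cdh23 (1.6), Akap5 (1.29), Ankrd2 (-4.63), Cxcl3 (-3.68), Gbp10 (-3.99), Car9 (-2.91), Fosl1 (-2.77), Il1r2 (-2.88) and Il6 (-2.4).

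**Figure D3:**
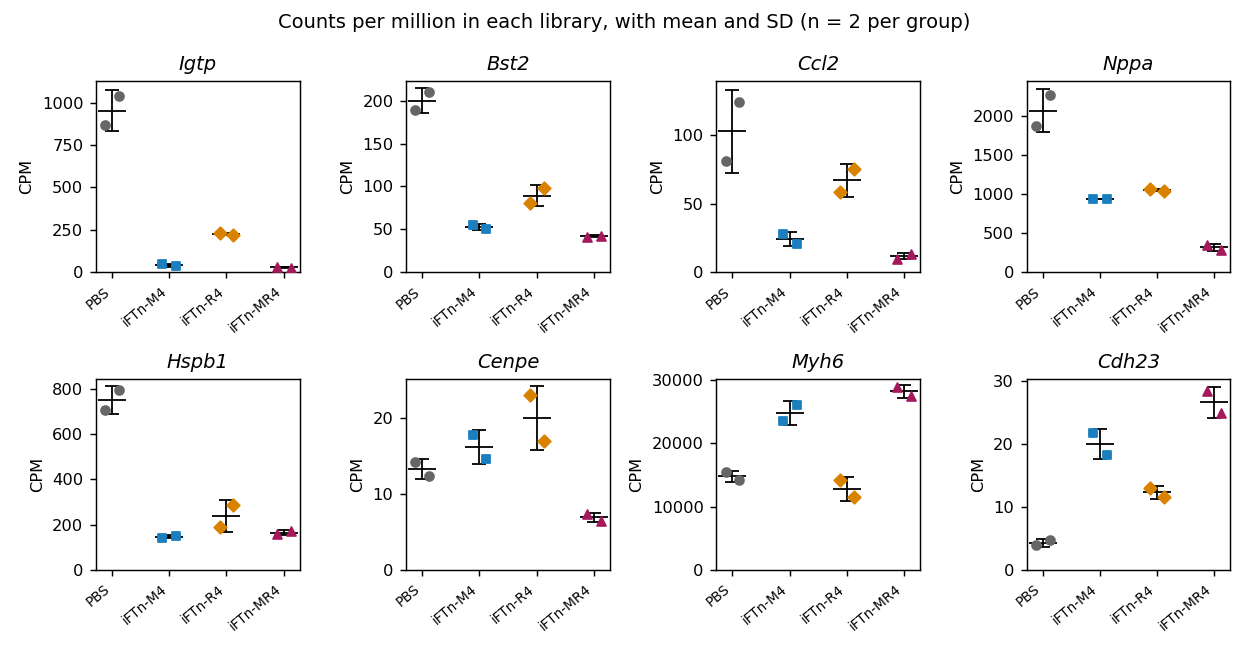
CPM (vertical axes) of Igtp, Bst2, Ccl2, Nppa, Hspb1, Cenpe, Myh6 and Cdh23 by group, with 1 point per library and the mean and SD of 2 libraries. Bst2 and Ccl2 are lowest in iFTn-MR4, and Myh6 and Cdh23 are highest there. Igtp and Myh6 have split counts.

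Across the 3 nanocages, 1474 genes rose and 1516 fell against PBS in every comparison, and 8 passed all 3 tests with mixed signs. With the length offset 647 rose and 803 fell in all 3, of which 484 and 606 also did so without it. Fold changes against PBS correlated at 0.75 between iFTn-M4 and iFTn-R4, 0.89 between iFTn-M4 and iFTn-MR4 and 0.69 between iFTn-R4 and iFTn-MR4. Simulated unchanged groups against the same controls gave 0.49, 0.48 and 0.49. Covariances were 0.22, 0.409 and 0.243 against a simulated 0.031, which leaves 0.19, 0.378 and 0.212. Genes that rose in both of a pair numbered 1592, 2403 and 1590, where independent lists would share 385, 679 and 478. Genes that fell in both numbered 1702, 2628 and 1594, against 460, 783 and 565. Simulated unchanged groups shared 0 to 0.1 genes in either direction. Without changed genes the adjusted threshold is stricter than in the data, so these counts do not measure what shared controls add to the overlaps. The 2 PBS libraries were not divided between comparisons, which would leave 1 to each, so part of the excess may come from the shared controls. All 3 comparisons also share the difference between the 2 tables, which the simulation did not hold. Part of the correlations, covariances and overlaps may come from that difference, and it cannot be told apart from an effect common to the nanocages. The mean of the 3 nanocages against PBS gave 3310 rises and 3654 falls, against 5000 and 1951 in limma-trend on TPM (median of all genes 0.148), and 4518 changed genes without PBS replicate 1.

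iFTn-MR4 against iFTn-R4 compares nanocages held in the same table and gave 1758 rises and 2043 falls. Library size alone gave 1148 and 2850 (median of all genes -0.100), limma-trend on TPM 963 and 2840 (-0.113), and leaving out iFTn-MR4 replicate 1 or 2 lowered the total to 1670 or 1635. The cell cycle list fell in all 36 of its genes, with a median of -1.25 (camera adjusted p = 5.34e-14, adjusted p = 0.46 with an estimated correlation). Cenpe, the motor that holds chromosomes to the spindle, fell 2.9-fold, at 6.9 ± 0.618 against 20 ± 4.26 CPM (-1.54 ± 0.18, edgeR adjusted p = 0.000658, Entrez gene 229841, chromosome 3, 135212563 to 135273540). Il1r2, a decoy receptor carried by neutrophils, fell 7.96-fold, at 0.896 ± 0.412 against 7.21 ± 0.154 CPM (-2.99 ± 0.31, Entrez gene 16178, chromosome 1, 40084692 to 40125230). Myh6 rose 2.21-fold, at 28290 ± 1056 against 12810 ± 1885 CPM (1.14 ± 0.13, Entrez gene 17888, chromosome 14, 54941921 to 54968017, split counts).

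Interferon response genes fell in 28 of 28 cases (camera adjusted p = 1.96e-13, adjusted p = 0.45 with an estimated correlation), with Irf7 (-2.08 ± 0.14) and Bst2 (-1.1 ± 0.11). Outside the list, Igtp (-3.07 ± 0.15) and Gbp10 (-3.82 ± 0.49) fell, both with split counts. Neutrophil genes fell in 13 of 16 (camera adjusted p = 1.03e-07, adjusted p = 0.386 with an estimated correlation), with S100a8 (-2.22 ± 0.44) and Csf3r (-1.07 ± 0.19). Cytokines and chemokines gave 21 falls and 1 rise of 32 (camera adjusted p = 4.59e-07, adjusted p = 0.386 with an estimated correlation), with Ccl2 (11.5 ± 2.4 against 67.1 ± 12.1 CPM, -2.54 ± 0.25), Il1b (-1.62 ± 0.38) and Spp1 (-2.02 ± 0.2). Il6 did not pass (-2.32 ± 0.84, edgeR adjusted p = 0.0665). Monocyte genes fell in 14 of 22 (camera adjusted p = 0.000646, adjusted p = 0.413 with an estimated correlation), with Plac8 (-2.44 ± 0.22). Gzma fell (-2.82 ± 0.32), and so did AA467197 (-3.43 ± 0.33). MHC class II genes went the other way, 4 of 8 rising with a median of 0.74 (camera adjusted p = 0.0282, adjusted p = 0.598 with an estimated correlation, fry adjusted p = 0.139). Gpr34, a lipid receptor of macrophages, rose (1.81 ± 0.28).

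Complex I rose in 32 of 37 cases (camera adjusted p = 1.32e-10, adjusted p = 0.46 with an estimated correlation), with Ndufs7 (0.64 ± 0.1) and Ndufv1 (0.55 ± 0.09). Complexes II to IV rose in 16 of 26 (camera adjusted p = 8.92e-08, adjusted p = 0.46 with an estimated correlation), with Cox6a2 (0.72 ± 0.09). TCA cycle genes rose in 21 of 22 (camera adjusted p = 5.79e-10, adjusted p = 0.46 with an estimated correlation), with Pdhb (0.7 ± 0.09). Cardiomyocyte genes rose in 13 of 20 (camera adjusted p = 1.46e-08, adjusted p = 0.386 with an estimated correlation), with the creatine kinase Ckm (0.96 ± 0.09) and myoglobin Mb (0.86 ± 0.09). Sarcomere genes rose in 13 of 22 (camera adjusted p = 8.06e-07, adjusted p = 0.413 with an estimated correlation), with troponin Tnni3 (0.76 ± 0.11). Myl4 (2.33 ± 0.65), the G protein subunit Gnb3 (1.91 ± 0.22) and the kinase Mylk4 (1.78 ± 0.23) rose too. The insulin-responsive glucose transporter Slc2a4 rose (0.99 ± 0.07) where Slc2a1 fell (-1.02 ± 0.12). Nppa (-1.73 ± 0.12) and Nppb (-0.48 ± 0.12) fell, and Myh7 did not pass (0.14 ± 0.32, split counts). Matrix proteases and inhibitors gave 13 falls and 3 rises of 21 (camera adjusted p = 0.000266, adjusted p = 0.386 with an estimated correlation), with Timp1 (-2.25 ± 0.2) and Adamts4 (-2.64 ± 0.18). Col1a1 (-0.4 ± 0.21), Col3a1 (-0.04 ± 0.17), Postn (0.03 ± 0.13) and Acta2 (-0.56 ± 0.27) did not pass.

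The mitochondrial superoxide dismutase Sod2 rose 1.47-fold, at 503 ± 4.41 against 343 ± 29.5 CPM (0.55 ± 0.09, edgeR adjusted p = 0.00318). Txn1 (-0.57 ± 0.07), Txnrd1 (-0.67 ± 0.1), Gsr (-0.85 ± 0.13), Gpx1 (-0.33 ± 0.1) and Hmox1 (-1.42 ± 0.24) fell. Superoxide and peroxide removal thus gave 4 rises and 8 falls of 22 and was not called by camera (adjusted p = 0.65). Sod1 (0.09 ± 0.09), Cat (0.02 ± 0.17), Nqo1 (0.12 ± 0.12), Fth1 (0.17 ± 0.12) and Ftl1 (-0.36 ± 0.12, split counts) did not pass. By edgeR adjusted p, the call of Gpx1 (0.0512 to 0.193 without iFTn-M4 replicate 1, either iFTn-R4 library or either iFTn-MR4 library), Myl4 (0.111 to 0.353 without iFTn-R4 replicate 1 or iFTn-MR4 replicate 1), Il1b (0.055 to 0.102 without iFTn-R4 replicate 1 or either iFTn-MR4 library), Nppb (0.0507 to 0.13 without iFTn-R4 replicate 2 or iFTn-MR4 replicate 1) and of S100a8 (0.0622 without iFTn-MR4 replicate 1) ended with a library left out. A call ended also in limma-voom for Myl4 (0.11), in limma-trend on TPM for Myl4 (0.0598), with only the groups compared for Myl4 (0.0731). Leaving out a library moved the fold over 1.5 times for Myl4 (log2 0.69 to 3.07 without iFTn-R4 replicate 2 or either iFTn-MR4 library) and Gbp10 (log2 -3.01 without iFTn-R4 replicate 2). On log2 of TPM the fold moved over 1.5 times for Gbp10 (-2.95) and Il1r2 (-2.35).

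**Figure D4:**
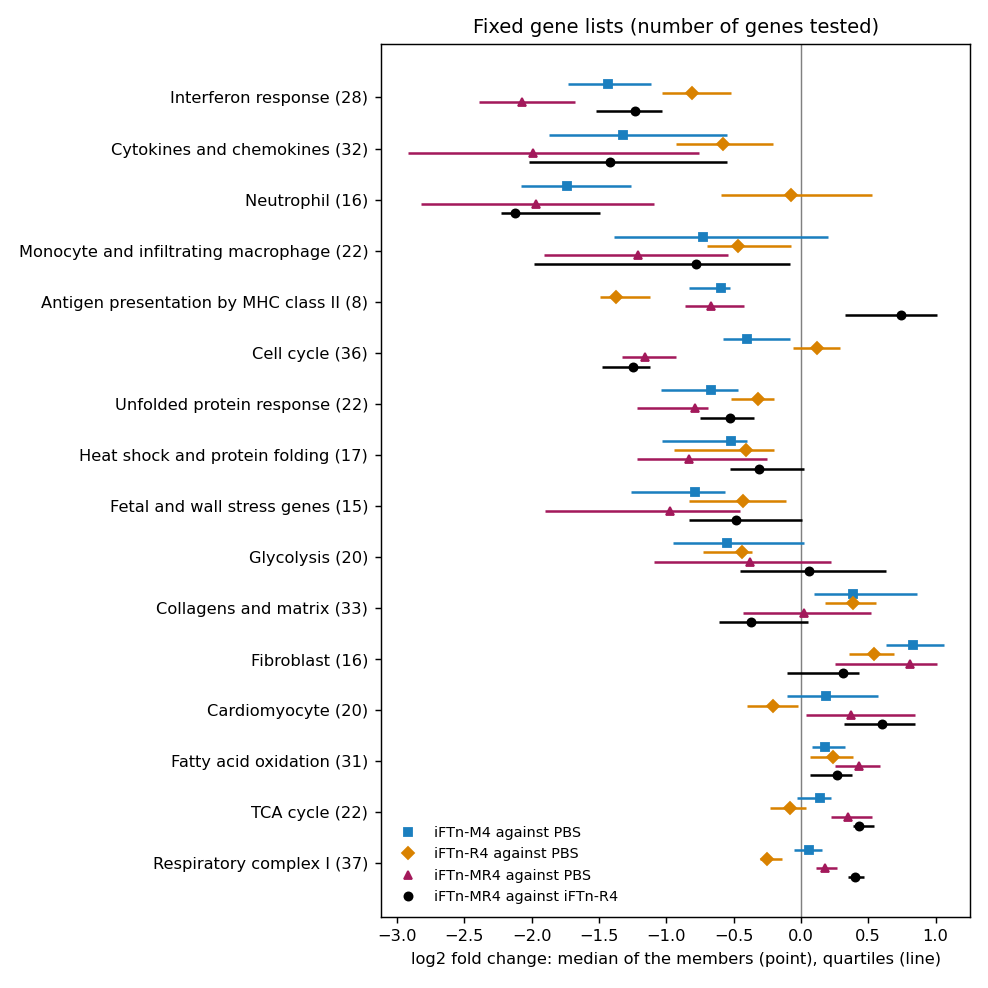
Log2 fold change (horizontal axis) of fixed gene lists in the 3 comparisons against PBS and in iFTn-MR4 against iFTn-R4, as the median (point) and quartiles (line) of the members. Interferon response genes lie below 0 in all 4 comparisons, and MHC class II genes lie below 0 against PBS but above 0 in iFTn-MR4 against iFTn-R4.

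iFTn-MR4 against iFTn-M4 had 3 genes that rose and 48 that fell. The split depended on the fit, with 81 and 271 in DESeq2, 235 and 479 with only the groups compared, 198 and 395 without iFTn-R4 replicate 1 and 214 and 389 without iFTn-R4 replicate 2. Nppa fell 2.95-fold, at 317 ± 47.4 against 936 ± 4.35 CPM (-1.56 ± 0.12, edgeR adjusted p = 0.00143). Adam8, a metalloproteinase of leukocytes, fell at 31.9 ± 1.5 against 81.3 ± 3.11 CPM (-1.35 ± 0.09, Entrez gene 11501, chromosome 7, 139978932 to 139995207). The interleukin 7 receptor Il7r (-1.54 ± 0.2), Cenpe (-1.23 ± 0.19), Lgals3 (-1.16 ± 0.09), Spp1 (-1.16 ± 0.2), Ccn2 (-0.76 ± 0.11) and Ftl1 (-0.76 ± 0.12, split counts) fell. The calcium channel inhibitor Rrad (0.69 ± 0.09) and Slc2a4 (0.44 ± 0.07) rose. Dgke (0.52 ± 0.09), Pm20d2 (0.5 ± 0.09) and Adhfe1 (0.48 ± 0.08), next in line among higher genes, did not pass (edgeR adjusted p = 0.052, 0.0525 and 0.0525). Nor did Sod1 (-0.01 ± 0.09), Sod2 (0.26 ± 0.09), Cat (0.15 ± 0.17), Gpx1 (-0.3 ± 0.1), Hmox1 (-1.09 ± 0.24), Nqo1 (0.12 ± 0.12), Fth1 (-0.05 ± 0.12), Nppb (-0.19 ± 0.12), Myh6 (0.19 ± 0.13, split counts) or Myh7 (0.66 ± 0.32, split counts). Il1b (-0.23 ± 0.42), Il6 (-1.22 ± 0.95), Ccl2 (-1.05 ± 0.26), S100a8 (-0.59 ± 0.49), Col1a1 (-0.58 ± 0.21), Col3a1 (-0.35 ± 0.17), Postn (-0.47 ± 0.13), Acta2 (-0.55 ± 0.27) and Timp1 (-0.94 ± 0.2) also stayed above the threshold.

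For gene lists the tests disagreed here, as camera with its preset correlation called 28 of 53, and both fry and camera with an estimated correlation called 0. Over all genes 1 of 36 cell cycle genes fell, but 32 did when adjusted over the list alone (median -0.83, camera adjusted p = 7.85e-16, adjusted p = 0.454 with an estimated correlation, fry adjusted p = 0.133). Interferon response genes gave no call over all genes in edgeR and 23 falls over the list alone (median -0.62, camera adjusted p = 3.22e-10, adjusted p = 0.454 with an estimated correlation, fry adjusted p = 0.148). Collagens and matrix gave none in edgeR and 20 falls (median -0.42, camera adjusted p = 6.42e-10, adjusted p = 0.454 with an estimated correlation, fry adjusted p = 0.131). Monocyte and infiltrating macrophage genes gave 5 falls, including Cd68 (-0.67 ± 0.08), and 11 over the list (camera adjusted p = 4.16e-08, adjusted p = 0.452 with an estimated correlation, fry adjusted p = 0.095). TCA cycle genes gave no call in edgeR and 12 rises over the list (median 0.23, camera adjusted p = 4.97e-09, adjusted p = 0.454 with an estimated correlation, fry adjusted p = 0.131). All calls named here but those of Nppa and Adam8 ended with 1 library left out: the highest adjusted p was 0.398 for Slc2a4 (without iFTn-MR4 replicate 2), 0.368 for Cenpe (without iFTn-MR4 replicate 2), 0.425 for Spp1 (without iFTn-M4 replicate 1), 0.368 for Ccn2 (without iFTn-MR4 replicate 2), 0.404 for Ftl1 (without iFTn-M4 replicate 1), 0.193 for Rrad (without iFTn-MR4 replicate 2), 0.23 for Il7r (without iFTn-MR4 replicate 2), 0.204 for Cd68 (without iFTn-MR4 replicate 1) and 0.067 for Lgals3 (without iFTn-MR4 replicate 1). A call ended also with the length offset for Spp1 (0.0535) and Ftl1 (0.0538), in limma-voom for Spp1 (0.0544), Ftl1 (0.0524), Slc2a4 (0.0547) and Cenpe (0.0658), in limma-trend on TPM for Spp1 (0.0726), Ftl1 (0.0726), Slc2a4 (0.0726) and Cenpe (0.102), with library size alone for Slc2a4 (0.052), with RLE factors for Spp1 (0.0508), with a mean of at least 10 counts for Spp1 (0.0513). The number of genes called ranged from 2 without iFTn-MR4 replicate 1 to 603 without iFTn-R4 replicate 2.

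iFTn-R4 against iFTn-M4 gave 478 rises and 349 falls. Library size alone gave 629 and 254, limma-trend on TPM 593 and 167, and only the groups compared 140 and 66. The total was 303 without iFTn-M4 replicate 1, 60 without iFTn-M4 replicate 2, 495 without either iFTn-MR4 library and 1379 without iFTn-R4 replicate 2. Inhbb, a subunit of activin, rose 5.95-fold, at 34.7 ± 0.405 against 5.83 ± 0.254 CPM (2.57 ± 0.16, edgeR adjusted p = 7.52e-05, Entrez gene 16324, chromosome 1, 119415463 to 119422248). Igtp rose 5.73-fold, at 224 ± 8.48 against 39.1 ± 7.49 CPM (2.52 ± 0.14, split counts), beside Gbp10 (3.31 ± 0.46, split counts) and Cyp26b1 (3.19 ± 0.77). Ptn, the growth factor pleiotrophin, fell 2.91-fold, at 18.5 ± 5.37 against 54.1 ± 4.96 CPM (-1.54 ± 0.18, Entrez gene 19242, chromosome 6, 36714924 to 36810179). The neuronal growth gene Nrn1 (-1.73 ± 0.32), the clock output factor Dbp (-1.48 ± 0.34) and Mylk4 (-1.34 ± 0.23) fell too.

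Interferon response genes rose in 10 of 28 cases, 19 over the list alone (camera adjusted p = 2.85e-10, adjusted p = 0.498 with an estimated correlation, fry adjusted p = 0.103), with Irf7 (1.64 ± 0.14) and Irf1 (0.82 ± 0.09). Neutrophil genes rose in 6 of 16, and in all 16 over the list alone (camera adjusted p = 2.85e-10, adjusted p = 0.34 with an estimated correlation), with Slfn4 (1.33 ± 0.17, split counts). Unfolded protein response genes rose in 12 of 22 (camera adjusted p = 3.93e-10, adjusted p = 0.34 with an estimated correlation), with Pdia4 (0.66 ± 0.08) and Hyou1 (0.6 ± 0.09). Cytokines and chemokines rose in 8 of 32 (camera adjusted p = 1.17e-05, adjusted p = 0.34 with an estimated correlation), with Ccl2 (67.1 ± 12.1 against 24 ± 5.15 CPM, 1.48 ± 0.23). Timp1 (1.32 ± 0.19), Adamts4 (1.93 ± 0.16), Spp1 (0.86 ± 0.19) and the growth factors Pgf (1.49 ± 0.1) and Apln (1.59 ± 0.19) rose. Cardiomyocyte genes fell in 10 of 20 (camera adjusted p = 5.47e-08, adjusted p = 0.36 with an estimated correlation), with Myh6 (-0.96 ± 0.13, split counts), and complex I in 3 of 37, or 16 over the list (camera adjusted p = 3.93e-10, adjusted p = 0.498 with an estimated correlation, fry adjusted p = 0.129). Dpt (-0.68 ± 0.08) and the growth factor Igf1 (-0.9 ± 0.12) fell. Of the NRF2 targets, the 4 with the lowest adjusted p that met the naming rule rose. They were Txnrd1 (0.64 ± 0.1), Gsr (0.7 ± 0.13), Osgin1 (0.95 ± 0.19) and Mt2 (1.61 ± 0.3). Sod1 (-0.1 ± 0.09), Sod2 (-0.3 ± 0.09), Cat (0.14 ± 0.17), Gpx1 (0.02 ± 0.1), Hmox1 (0.32 ± 0.23), Nqo1 (0.00 ± 0.12), Fth1 (-0.22 ± 0.12) and Ftl1 (-0.4 ± 0.12, split counts) did not pass. The same holds for Nppa (0.17 ± 0.12), Nppb (0.29 ± 0.12), Myh7 (0.52 ± 0.32, split counts), Il1b (1.4 ± 0.37), Il6 (1.1 ± 0.7), S100a8 (1.63 ± 0.42), Col1a1 (-0.19 ± 0.21), Col3a1 (-0.31 ± 0.17), Postn (-0.5 ± 0.13) and Acta2 (0.01 ± 0.27). Of these, S100a8 (edgeR adjusted p = 0.0299) and Postn (0.0418) passed with the length offset. By edgeR adjusted p, the call of Cyp26b1 (0.0623 to 0.201 without either PBS library, either iFTn-M4 library, iFTn-R4 replicate 1 or either iFTn-MR4 library), Dbp (0.0562 to 0.164 without either PBS library, either iFTn-M4 library or either iFTn-MR4 library), Nrn1 (0.057 to 0.0979 without either iFTn-M4 library), Mylk4 (0.0612 to 0.074 without either iFTn-M4 library), Spp1 (0.0658 to 0.228 without either iFTn-M4 library or iFTn-R4 replicate 2), Gbp10 (0.0703 without iFTn-M4 replicate 2), Ccl2 (0.091 without iFTn-M4 replicate 2), Myh6 (0.0703 without iFTn-M4 replicate 2) and of Timp1 (0.0675 without iFTn-M4 replicate 2) ended with a library left out. A call ended also in DESeq2 for Dbp (0.0531), in limma-voom for Cyp26b1 (0.146), in limma-trend on TPM for Dbp (0.0594) and Cyp26b1 (0.0819), with only the groups compared for Dbp (0.124), Cyp26b1 (0.135), Mylk4 (0.0571) and Myh6 (0.07). Leaving out a library moved the fold over 1.5 times for Cyp26b1 (log2 1.25 to 4.36 without either iFTn-M4 library or either iFTn-R4 library), Dbp (log2 -2.4 without iFTn-R4 replicate 1) and Gbp10 (log2 2.51 without iFTn-R4 replicate 2). On log2 of TPM the fold moved over 1.5 times for Gbp10 (2.65) and Cyp26b1 (2.56).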

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

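All tests of explanations in this part were chosen only after the results had been seen. Some genes are listed in the nanocage table alone and so entered no comparison. Xntrpc had a mean expected count of 21.4 in iFTn-M4, with 17.12 and 25.62 in its libraries and 0 in the 4 other nanocage libraries. Duxbl3 had 9.32 in iFTn-M4, but 2.44 and 20.17 in the libraries of iFTn-MR4, so it does not stand out there. LOC100862043 had 8.2 in iFTn-M4. Luzp2 had 6.0 in iFTn-MR4, and Tmem232 5.0, Rspo3 4.5 and LOC115489962 3.59 in iFTn-R4. Each is the mean of a group in which both libraries held more than 3 counts, the limit that a count of 0 allows, and all rest on few counts.

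The fall of interferon response genes against PBS was weighed first, because PBS has a table of its own. If the table were the whole cause, the nanocage groups would be shifted alike, but the list's median in iFTn-MR4 against iFTn-R4, which share a table, was -1.23 (quartiles -1.52 to -1.03). That excludes the table as the whole cause for iFTn-MR4. For iFTn-R4 the median against PBS was -0.81 (quartiles -1.03 to -0.52), and with 0 tables that hold both groups the table and the treatment cannot be told apart. The length trend was excluded as well, since with the offset the median in iFTn-MR4 against PBS was -1.99 (quartiles -2.45 to -1.71).

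Higher long genes and lower short genes against PBS were weighed next. The difference between the longest and shortest quintile was 0.54 to 0.58 in the 3 comparisons, a range of 0.04, and 0.05 in iFTn-MR4 against iFTn-R4. A difference in RNA, library preparation or processing between the tables may account for it, since such a cause would act alike on all 3. An effect common to the nanocages would also act alike on all 3. Because the PBS libraries are in a table of their own, these causes cannot be told apart. The value of 0.05 is small beside 0.54 to 0.58, so most of the trend is not part of the graded change in which iFTn-MR4 lies furthest from PBS. A small graded part is not excluded, as the limit for this test was set after the values were seen.

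Lower leukocyte and cell cycle genes with higher cardiomyocyte genes in iFTn-MR4 against iFTn-R4 were the last pattern. A larger share of cardiomyocyte RNA as the whole cause would lower all other cell types alike. Fibroblast markers (lower quartile -0.1) instead lay above neutrophil markers (upper quartile -1.49), their medians 2.43 apart, which excludes it. Fewer leukocytes of every type would lower the MHC class II genes if their expression per cell were unchanged, but their median was 0.74 (quartiles 0.33 to 1.01). Expression of these genes per cell may differ between groups, so they cannot exclude fewer leukocytes of every type. A smaller share of some or all leukocytes, changed expression per cell, or both remain possible, and bulk RNA cannot tell them apart.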

How the results depend on the processing

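The length offset, its use with a log2 fold change of at least 1, and the fit without genes with split counts were tests chosen only after the results had been seen. Counts of changed genes below are in the order iFTn-M4, iFTn-R4 and iFTn-MR4 against PBS, iFTn-MR4 against iFTn-M4 and against iFTn-R4, iFTn-R4 against iFTn-M4, and the mean of the 3 nanocages against PBS. They were 5745, 4096, 7096, 51, 3801, 827 and 6964 in edgeR, 974, 340, 1592, 13, 682, 153 and 832 with a log2 fold change of at least 1, and 850, 239, 1385, 10, 674, 160 and 746 with the length offset as well. The length offset alone gave 4584, 1951, 6225, 42, 3867, 838 and 5618, and 62%, 37% and 70.7% of the genes called against PBS remained called with it. Of those that remained, all kept their sign for iFTn-M4 and iFTn-R4, and 5003 of 5016 did for iFTn-MR4. Fitting only the groups compared gave 6156, 2528, 7674, 714, 2738 and 206 for the 6 pairs of groups, in the same order. Comparisons with iFTn-R4, whose replicates lay furthest apart, had fewer calls than in the fit of all 8 libraries. Those without iFTn-R4 had more. The fit of all 8 libraries shares 1 estimate of spread per gene among the groups. For iFTn-MR4 against iFTn-M4, DESeq2 gave 352, limma-voom 26 and limma-trend on TPM 22. With each library left out in turn the counts ranged over 3560 to 6461, 2055 to 4065, 5059 to 7684, 2 to 603, 1635 to 4204, 60 to 1379 and 4518 to 7525, where a lone library was assumed to vary like the other groups. The lowest counts came without iFTn-M4 replicate 2, PBS replicate 2, iFTn-MR4 replicate 1, iFTn-MR4 replicate 1, iFTn-MR4 replicate 2, iFTn-M4 replicate 2 and PBS replicate 1. For iFTn-MR4 against iFTn-M4 the count was 26 without PBS replicate 1, 22 without PBS replicate 2, 3 without iFTn-M4 replicate 1, 24 without iFTn-M4 replicate 2, 593 without iFTn-R4 replicate 1, 603 without iFTn-R4 replicate 2, 2 without iFTn-MR4 replicate 1 and 4 without iFTn-MR4 replicate 2. Gene list calls ranged from 166 to 200 of 378 with a library left out, against 177 of 371 with all 8 libraries. Both extremes had 54 lists with enough tested members instead of 53. With all 8 libraries, camera with an estimated correlation gave 0, or 27 at an unadjusted p under 0.05. In the order above, camera called 19, 18, 29, 28, 29, 29 and 25 of 53 lists and fry 23, 14, 33, 0, 28, 11 and 28. The replicate block, that is the replicate number as a term, gave 271 genes for iFTn-MR4 against iFTn-M4, 65 higher and 206 lower. Deviations of libraries with the same number correlated at -0.014 to 0.153, over 0.1 in 3 of the 6 pairs of groups, and the labels give no shared origin, so the libraries were not treated as pairs. Of the named calls, that of Cyp26b1 in iFTn-R4 against iFTn-M4 did not pass with the replicate block (adjusted p = 0.0544). Of 317 named values followed through the alternatives 239 passed, of which 43 lost the call under at least 1 alternative other than the fold threshold, 43 of them with a library left out and 9 with the length offset, and none changed sign (0 in edgeR, DESeq2 and limma). A log2 fold change of at least 1 would end 65 of the 239 calls. List genes with stable calls were named by preference after their values were seen, so calls may be lost more often among all called genes. Calls were gained too: of named values that had not passed, 7 passed with the length offset and 13 in DESeq2. Neither the prior count of 2 for log2 CPM nor the pseudocount of 1 for log2 of TPM was varied. The cause was not tested for these differences or for the reversals that follow, all in genes that did not pass.

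By library size alone, the log2 fold change reversed for Fth1 (-0.03) in iFTn-MR4 against PBS, Sod1 (-0.00), Cat (-0.07) and Postn (-0.06) in iFTn-MR4 against iFTn-R4. In limma-voom, the log2 fold change reversed for Nqo1 (-0.01) and Acta2 (-0.05) in iFTn-R4 against iFTn-M4. With only the groups compared, the log2 fold change reversed for Fth1 (-0.01) in iFTn-MR4 against PBS. With the replicate block, the log2 fold change reversed for Acta2 (-0.01) in iFTn-R4 against iFTn-M4. In limma-trend on TPM, the log2 fold change reversed for Sod2 (0.16) and Cat (0.14) in iFTn-M4 against PBS, Fth1 (0.04) and Myh6 (0.05) in iFTn-R4 against PBS, Sod1 (-0.01), Cat (-0.06) and Postn (-0.08) in iFTn-MR4 against iFTn-R4, Sod1 (0.00) in iFTn-R4 against iFTn-M4. With the length offset, the log2 fold change reversed for Sod1 (0.09) and Cat (0.07) in iFTn-M4 against PBS, Sod1 (0.08) and Fth1 (0.14) in iFTn-R4 against PBS, Sod1 (0.14) and Col1a1 (-0.14) in iFTn-MR4 against PBS, Sod1 (0.05) in iFTn-MR4 against iFTn-M4. With a library left out, iFTn-M4 against PBS gave both signs for Sod2 (-0.12 to 0.05), Cat (-0.10 to 0.00) and Ftl1 (-0.10 to 0.19). With a library left out, iFTn-R4 against PBS gave both signs for Spp1 (-0.16 to 0.20), Cat (-0.28 to 0.38) and Nqo1 (-0.07 to 0.30). With a library left out, iFTn-MR4 against PBS gave both signs for Fth1 (-0.01 to 0.02). The same was seen in iFTn-MR4 against iFTn-M4 for Sod1 (-0.10 to 0.08), Il1b (-0.69 to 0.43) and S100a8 (-1.29 to 0.76). The same was seen in iFTn-MR4 against iFTn-R4 for Cat (-0.27 to 0.38), Nqo1 (-0.06 to 0.31), Col3a1 (-0.24 to 0.21), Postn (-0.13 to 0.22), Sod1 (-0.01 to 0.17) and Myh7 (-0.05 to 0.29). The same was seen in iFTn-R4 against iFTn-M4 for Nqo1 (-0.19 to 0.17), Col1a1 (-0.57 to 0.11), Gpx1 (-0.07 to 0.12), Acta2 (-0.51 to 0.39), Hmox1 (-0.07 to 0.63) and Cat (-0.22 to 0.42).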

Other observations

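Of the tests in this part, only camera with the length trend subtracted was chosen after the results had been seen. In iFTn-M4 against PBS 10 of 15 circadian clock genes rose and 1 fell (camera adjusted p = 0.0139, adjusted p = 0.395 with an estimated correlation), with the clock output factor Hlf (35.8 ± 3.93 against 16 ± 0.862 CPM, log2 fold change 1.16 ± 0.13), the repressor Nr1d2 (1.03 ± 0.11) and Per3 (1.24 ± 0.16). In iFTn-MR4 against PBS 8 rose and 1 fell (camera adjusted p = 0.0229, adjusted p = 0.385 with an estimated correlation, 0.0857 with the length trend subtracted), with Hlf at 1.32 ± 0.13. Against iFTn-R4 iFTn-MR4 had 7 rises and no fall in edgeR (camera adjusted p = 0.00339, adjusted p = 0.386 with an estimated correlation), with Tef at 0.82 ± 0.13. In iFTn-R4 against PBS 2 rose, 1 fell and 12 did not pass (camera adjusted p = 0.465), and in iFTn-R4 against iFTn-M4 6 fell and none rose (camera adjusted p = 0.000259, adjusted p = 0.34 with an estimated correlation). In iFTn-MR4 against iFTn-M4 none of the 15 passed in edgeR (camera adjusted p = 0.634). The labels give no hour of tissue collection.

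In iFTn-MR4 against PBS 5 of 12 epicardium and mesothelium genes fell and none rose (camera adjusted p = 0.0581), with the retinoic acid enzyme Aldh1a2 at 44.9 ± 3.7 against 139 ± 14.1 CPM (-1.63 ± 0.14). Of 20 angiogenesis genes 9 rose and 5 fell (camera adjusted p = 0.394). The vessel growth factors Pgf (-2.18 ± 0.1) and Apln (-2.41 ± 0.19) fell there, while the angiopoietin receptor Tek (0.75 ± 0.09) rose. Complement genes gave 6 rises and 5 falls of 16 in the same comparison (camera adjusted p = 0.755). C3 rose in iFTn-M4 (1.64 ± 0.11) and in iFTn-MR4 (1.64 ± 0.11) as it did in iFTn-R4, while complement factor Cfb fell in iFTn-MR4 (-1.39 ± 0.13). Smooth muscle and pericyte genes gave 7 rises and 3 falls of 14 in iFTn-MR4 against PBS (camera adjusted p = 0.156). The mural cell potassium channel subunit Abcc9 (1.48 ± 0.1) and the smooth muscle myosin Myh11 (1.23 ± 0.12) rose. Of 16 p53 targets 11 fell and 3 rose there (camera adjusted p = 0.00985, adjusted p = 0.385 with an estimated correlation), with Cdkn1a (-1.82 ± 0.18) and Bax (-1.12 ± 0.1) among the falls and Sesn1 (1.11 ± 0.09) among the rises.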
